A study of Mus musculus with 24 samples.

How the data were processed

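The study profiled accessible chromatin by ATAC-seq in 24 samples of sorted skin cells from mice of a CD1 and C57BL/6J cross, per the labels. Unwounded cells and the cells of the partial-thickness wound came from Krt19-CreER/R26-YFP mice and those of the full-thickness wound from Sox9-CreER/R26-YFP mice. Per the labels' protocols, skin was treated with trypsin, cells were sorted by FACS, lysed and exposed to the transposase, and the DNA was amplified by PCR. The gates of the sort are not given in the sources used here.

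The data analysed were 8 deposited peak lists, 1 per group, of narrowPeak layout. Bowtie, Picard, MACS2 2.1.1.20160309 and bedtools 2.29.2 were named, with the mm10 build, per the submitters' processing notes, which give no role or order of these tools. Whether peaks were called on pooled reads of a group or merged from calls per sample is not given in the sources used here. Each deposited peak has a score, which equals 10 times its −log10 q in nearly all peaks. The fold enrichment of a deposited peak is a ratio over the local background of its own list, as its caller writes it. The deposited −log10 p and −log10 q values likewise belong to the peak within its own list. All of these values are the authors', and they were used only to describe, rank or filter peaks within a list. Gaps in the numbering of the peaks show that the authors kept part of the calls, from 32.8% in the day 3 partial-thickness list to 82.5% in the day 80 full-thickness list. The lowest −log10 p kept was 17.3 in the hair follicle list, 13.52 and 7.86 in the day 0 and day 80 epidermal lists, 39.7, 40.19 and 21.04 in the partial-thickness lists of days 3, 7 and 80, and 32.24 and 7.98 in the full-thickness lists of days 7 and 80. Per 1000000 units of the summed −log10 p of its list, this value lay between 9.7 and 12.9. Thresholds that differ in this way can move a weak region into or out of a list without any change in the cells. Read counts are not used here, so sequencing depth is unknown.

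Each list was matched to its group by the name it was deposited under. For the day 0 epidermal list this name stands against a control tag for day 7 in its peak names, which could not be settled from the sources used here.

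Peaks of all lists were merged into 63188 regions. A list held a region when one of its peaks overlapped it by at least 1 bp. Classes of regions were formed by presence and absence: hair follicle against day 0 epidermis in both directions, day 0 against day 80 epidermis, regions in an early wound list and neither day 0 list (wound-gained), and regions of a day 80 wound list in neither unwounded epidermal list. The share of a class in another list was given with its exact 95% Clopper-Pearson interval, and for overlaps of wound types with the number that independent lists would share. The half-width of a difference combined those of both shares as if they were independent. In many differences both are shares of the same regions, and this pairing was not used. With 1 list per group no test between groups was run. These classes, the gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. Chosen after values had been seen were the differences between shares, the deciles by score, the comparison of each list of a trio set apart from the others, the strong regions, the peaks on sex chromosomes, the finer classes built from these, and the choice of Lgr5 and Bmp4 for the locus maps.

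Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. The plan assigned regions to transcription start sites, but the table gives no strand, so the nearest protein-coding gene within 50 kb was used (distance 0 inside a gene), and regions within 1 kb of either gene end stood in for promoters. This assigned 52791 regions (83.5%) to 15667 genes, with a median of 2 regions per gene. The table gives no exons, so exonic, intronic and UTR positions were not analysed here. A planned count of transcription factor motifs needs genome sequence and was not run.

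The 18 gene lists were hair follicle stem cell, epidermal stem cell, basal keratinocyte, AP-1 and stress, wound epithelium, inflammation, interferon, proliferation, terminal differentiation, Wnt and hedgehog, BMP and TGF-beta, sebaceous gland and isthmus, immune, fibroblast, endothelial, melanocyte, muscle and housekeeping. Of the listed genes, 5 were not found in the table. The share of a list's regions that fell in a class was placed as a percentile among 10000 random gene lists of the same size matched on the number of regions per gene, a description of these lists and not a p-value. Genes were named by rule: the 10 with the most regions of a class (ties by the share of the gene's regions, then by name), up to 4 members of each gene list by the same order, and 16 fixed genes (Sox9, Lhx2, Nfatc1, Cd34, Krt15, Lgr5, Klf5, Gata3, Krt14, Trp63, Fosl1, Jun, Fos, Krt6a, Krt17 and Stat3). Long genes gather many regions, which places some of them high in several classes. Krt6b, the fibroblast genes without any region and the sex-linked genes fall outside this rule and were named after their values were seen.

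The steps were tested on simulated data. All 18 classes were recovered on 20000 simulated regions, 5.25% of 400 random gene lists fell outside the band of percentiles 2.5 to 97.5, and a planted list came out at percentile 100. Simulated peaks of the same region always overlapped and those of neighbouring regions never did. The recovery of classes therefore checks the counting only, not the effect of peak width or of thresholds that differ between lists. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.

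Results were recomputed with peaks that cover at least 50% of a region, lists of equal length (the 22023 peaks of highest score in each, 75% of the shortest list), absence only when no peak lies within 500 bp, autosomes only, peaks reduced to their central 200 bp, pairwise overlap of peaks without merging, merging only the lists compared, and with gene windows of 10 kb and 100 kb. The strong regions, with a peak in the upper 50% by score of a list that defines the class, the gene end version and the fibroblast list without Fbn1 were added after the data were seen.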

Results

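Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA, in stem cells sorted from mouse skin before and after wounding. The 24 samples fall into 8 groups. Unwounded skin gave hair follicle stem cells at day 0 (4 samples) and epidermal stem cells at day 0 (4 samples) and day 80 (3 samples). After a partial-thickness wound, cells labelled as progeny of hair follicle stem cells were taken at day 3 (3 samples), day 7 (2 samples) and day 80 (3 samples). After a full-thickness wound, cells labelled as progeny of epidermal stem cells were taken at day 7 (3 samples) and day 80 (2 samples). The mice of this wound carried Sox9-CreER, although Sox9 is a factor of hair follicle stem cells, and the labels do not say how their cells were assigned to the epidermis. The comparisons ask which accessible regions separate the hair follicle from the epidermis, which appear while a wound heals, and which remain at day 80, when the labelled cells are set beside unwounded epidermis.

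Each group came as 1 deposited peak list, so no error between replicates and no test between groups can be given, and a region is described as present in or absent from a list. Shares carry exact Clopper-Pearson 95% intervals that cover counting error only. The hair follicle list held 29365 peaks, the day 0 and day 80 epidermal lists 30974 and 32236, the partial-thickness lists 36222 at day 3, 35430 at day 7 and 32976 at day 80, and the full-thickness lists 37214 at day 7 and 33573 at day 80. Read depth per sample is unknown. The lists differed in how strong their weakest peak was, from a −log10 p of 7.86 in the day 80 epidermal list to 40.19 in the day 7 partial-thickness list, and in peak width, from a median of 460 bp in the day 80 full-thickness list to 987 bp in the day 3 partial-thickness list. The day 0 epidermal list rests on the name it was deposited under, since its peak names carry a control tag for day 7, a day for which the labels hold no unwounded group.

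Merging all 267990 peaks gave 63188 regions on the mm10 build, with a median width of 951 bp. All 8 lists held 13929 of them (22%), and 52.2% of these common regions lay within 1 kb of a gene end. Regions were assigned to the nearest protein-coding gene within 50 kb, which places a region near a gene without showing that it acts on it. The 2 unwounded epidermal lists shared 71.0% of the regions held by either. The hair follicle list shared 44.1% with the day 0 epidermal list. The day 3 and day 7 partial-thickness lists shared 72.2%, the day 7 lists of the 2 wound types 64.9%, and the day 80 lists of the 2 wound types 67.2%. Each day 80 wound list stood close to unwounded epidermis, with 67.6% (partial) and 68.2% (full) shared with the day 0 epidermal list and 68.8% and 66.8% with the day 80 epidermal list.

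Hair follicle and epidermal stem cells of unwounded skin differed at genes of the hair follicle stem cell programme. Lgr5, an R-spondin receptor that marks hair follicle stem cells (gene ID 14160, chromosome 10, 115450314 to 115587780), had 7 regions in the hair follicle list and 1 in the day 0 epidermal list. Cd34, a surface marker of the hair follicle bulge, had 4 against 2, Lhx2, a homeobox factor of the bulge, 6 against 3, Nfatc1, a factor of quiescent bulge cells, 10 against 7, Krt15 3 against 1, Foxc1 3 against 1 and Sox9 3 against 2. In the other direction, Bmp4, a secreted growth factor (gene ID 12159, chromosome 14, 46383525 to 46390669), had no region in the hair follicle list and 6 in the epidermal list. The transcription factor Gata3 had 3 against 6, Tgfb2, a TGF-beta ligand, 4 against 7, and its receptor gene Tgfbr2 5 against 10. Other genes of the same lists went the opposite way, with Klf4 at 7 against 3 and Smad7 at 8 against 3. As a set, BMP and TGF-beta genes had 29 regions in the hair follicle list alone of this pair and 34 in the epidermal list alone. Epidermal stem cell genes had 12 and 16.

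In all, 10897 regions were in the hair follicle list and not the day 0 epidermal list, and 12093 the other way round. Few lay within 1 kb of a gene end (10.9% and 7.7%). The protein-coding genes with the most hair follicle regions of this kind included the cell adhesion genes Tenm3 (15 regions) and Adgrl3 (15), the heparan sulfate proteoglycan gene Gpc6 (13) and the flippase gene Atp8a2 (14), beside long genes such as Rad51b (20) and Lpp (17). Gpc6 had 14 regions in the hair follicle list, 1 in the day 0 epidermal list and 0 in the day 80 epidermal list. On the epidermal side stood Dlg2, a membrane scaffold gene (21 regions), Robo1, a Slit receptor gene (15), Syt1 (14), Dab1 (13) and the growth hormone receptor gene Ghr (11). Robo1 had 2 regions in the hair follicle list and 17 in the day 0 epidermal list, and Dab1 had 1 and 14. Macrod2, a gene of very large span, led the epidermal side with 24 regions and also had 16 on the hair follicle side.

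Of 171 regions at 17 hair follicle stem cell genes, 60 (35.1%) were hair follicle regions absent from the day 0 epidermal list, and 16 of the 17 genes had at least 1. Random gene lists matched on regions per gene had a median of 18.8%, and the list stood at percentile 100 among 10000 of them. Of the same 171 regions, 9.9% were epidermal regions absent from the hair follicle list, at percentile 0.2. Inflammation genes held few of the hair follicle regions (9.9%, percentile 1.8), with percentile 18.8 when the window was 10 kb. Fibroblast genes held many, with 13 of 27 regions (48.1%, percentile 100), at Fbn1 (6), Col1a1 (2), Col1a2 (2) and Pdgfra (2) among others. Basal keratinocyte genes held few of the epidermal regions (12.0%, percentile 2.3), with percentile 5.0 when the window was 100 kb. Of 18 gene lists, 0.9 would fall outside the band that holds the central 95% of random lists in any class by chance. No list stood above this band in the epidermal regions absent from the hair follicle list. Within 1 kb of a gene end the hair follicle stem cell genes had 19 regions, 2 of them hair follicle regions, and stood at percentile 55.2.

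The unwounded epidermal lists of day 0 and day 80 give the background for every later comparison, as lists of the same kind of cell. The day 80 list is the list most like the day 0 list, with 71.0% shared. Choosing regions absent from the day 0 list can therefore lower the day 80 share. Part of an excess over this background can come from that choice. The genes of the basal keratinocyte list held more day 80 than day 0 regions. Trp63, which encodes the p63 factor of stratified epithelia, had 2 regions at day 0 and 10 at day 80, Col17a1, a hemidesmosome collagen gene, 1 and 5, Lama3, a laminin gene of the basement membrane, 5 and 8, and Krt5, a basal keratin gene, 0 and 2. Bmp4 (6 and 7), Tgfb2 (7 and 8), Tgfbr2 (10 and 10) and Robo1 (17 and 16) had similar numbers at both days. In all, 4595 regions were in the day 0 list alone of this pair and 5857 in the day 80 list alone. In strong regions, those with a peak in the upper 50% by score of the list, the counts were 365 and 350, so that nearly all of these differences lie in weak peaks. Among all 5857 regions of the day 80 list alone, basal keratinocyte genes held 16.5% of their regions, against a median of 9.9% for random lists (percentile 98.2). Trp63 by itself had 8 of these regions. In this class 1 of 18 gene lists left the band, about the 0.9 that chance would give. When peaks had to cover 50% of a region, 8285 regions were in the day 0 list alone of the pair, and with lists of equal length 3863 were in the day 80 list alone. The 50% rule thins lists with narrow peaks, leaving 76.8% of the regions of the day 0 epidermal list, 64.5% of the day 80 epidermal list, 93.7% of the day 80 partial-thickness list and 37.5% of the day 80 full-thickness list, so that differences between these lists under it follow peak width in part.

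The partial-thickness wound lists of days 3 and 7 held many hair follicle regions that unwounded epidermis lacked, and the day 80 list held few. Lgr5 had 7 regions at day 3, 7 at day 7 and 0 at day 80. Of its 6 hair follicle regions absent from the day 0 epidermal list, 4 were in both early wound lists, all inside the gene (chromosome 10, 115455536 to 115456565, 115468027 to 115469528, 115528111 to 115529396 and 115549834 to 115550688). A further pair of Lgr5 regions, at 115593027 to 115594056 and 115617377 to 115617708, was in the early wound lists and in no other list. Sox9, a factor of hair follicle stem cells, had 3 regions in the hair follicle list, 6 at day 3, 5 at day 7 and 2 at day 80, and Foxc1 had 3, 4, 2 and 0. Gpc6 had 14, 11, 10 and 2. A Cd34 region 42752 bp from the gene (chromosome 1, 194894918 to 194896068) was in the hair follicle, day 3 and day 7 lists alone.

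**Figure D1:**
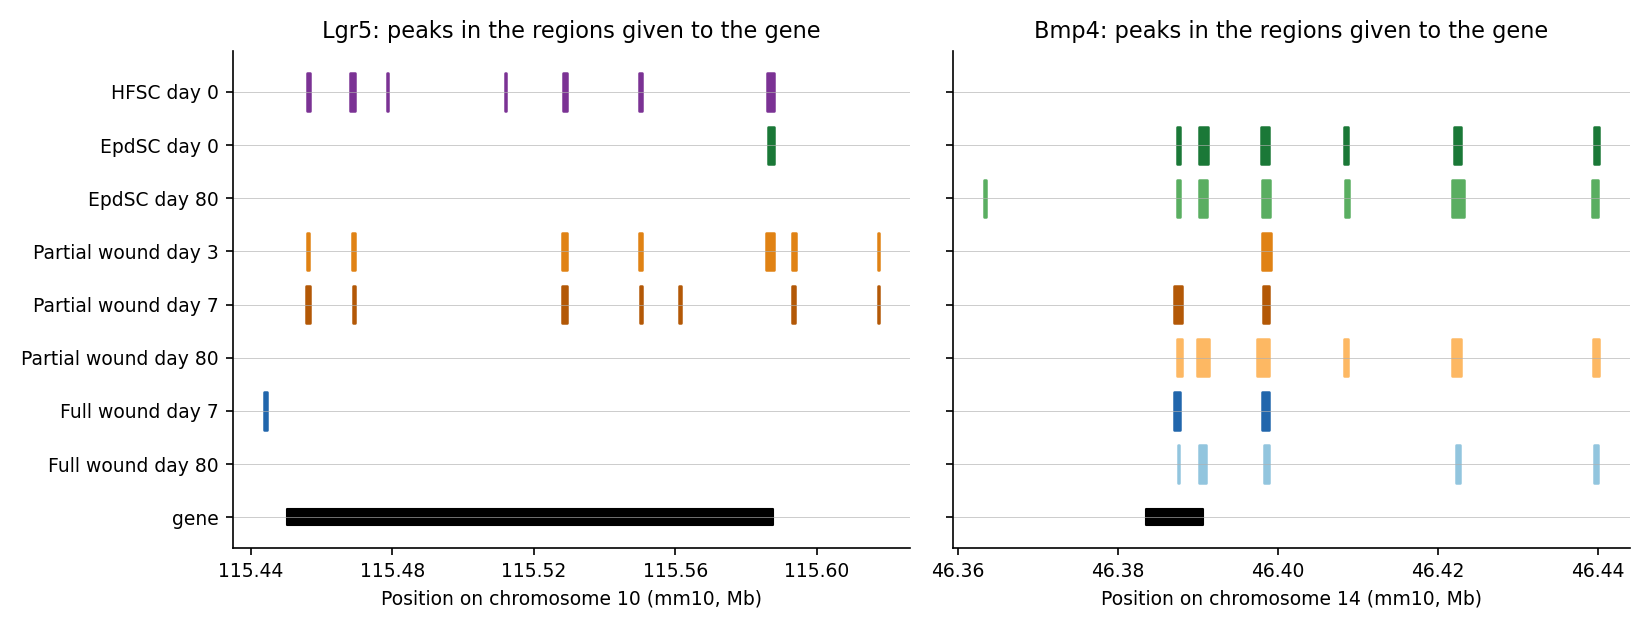
Peaks of the 8 lists (rows) in the regions given to Lgr5 (left, chromosome 10) and Bmp4 (right, chromosome 14), with position in Mb of mm10 along the axis and the gene span as a black bar. Lgr5 has 7 regions in the hair follicle list and in each early partial-thickness list and 0 in both day 80 wound lists, and Bmp4 has 0 in the hair follicle list and 6 in the day 0 epidermal and day 80 partial-thickness lists.

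Of the 10897 hair follicle regions absent from the day 0 epidermal list, 34.9% (95% interval 34.0 to 35.8) were in the day 3 list, 33.6% (32.7 to 34.5) in the day 7 list and 18.9% (18.2 to 19.7) in the day 80 list. The background in the day 80 epidermal list was 16.9% (16.2 to 17.6), a share that choosing regions absent from the similar day 0 list can lower. The full-thickness lists held 23.4% (22.6 to 24.2) at day 7 and 16.7% (16.0 to 17.4) at day 80, a smaller excess of the same direction at day 7. The day 3 share of the partial-thickness wound stood 18.1 percentage points above the background and the day 80 share 2.0 points (interval half-width 1.02). The 9060 hair follicle regions absent from both epidermal lists gave the same order, with 28.7%, 26.6% and 9.8%. Among the 60 hair follicle regions at hair follicle stem cell genes, 23 (38.3%) were in the day 3 list, 21 (35.0%) in the day 7 list and 4 (6.7%) in the day 80 list, and 4 were in the day 80 epidermal list. Of 27 at Wnt and hedgehog genes such as Lgr4 and Fzd7, the counts were 10, 12 and 1, with 5 in the day 80 epidermal list. Basal keratinocyte genes had 15 of 33 such regions in the day 80 list and 9 in the day 80 epidermal list. AP-1 and stress genes were similar, with 11 of 26 and 9, and these differences between gene lists were not tested. In strong regions the day 80 excess was 0.7 points, within its half-width of 1.77, and the day 3 excess 23.3 points. The 50% rule, which keeps more of the partial-thickness lists than of the day 80 epidermal list, gave 16.1 and 30.1 points.

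The hair follicle regions with the highest peak score in the hair follicle list were also those found most often in the early wound lists. In the lowest decile by score, 28.9% (26.2 to 31.7) were in the day 3 list, and in the highest decile 40.7% (37.8 to 43.7). In the day 80 partial-thickness list the highest decile had a share of 10.3% (8.5 to 12.2), and in the day 80 epidermal list 10.8% (9.0 to 12.8). The labels do not say whether the gates that isolated the wound cells left out hair follicle stem cells still in the follicle.

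**Figure D2:**
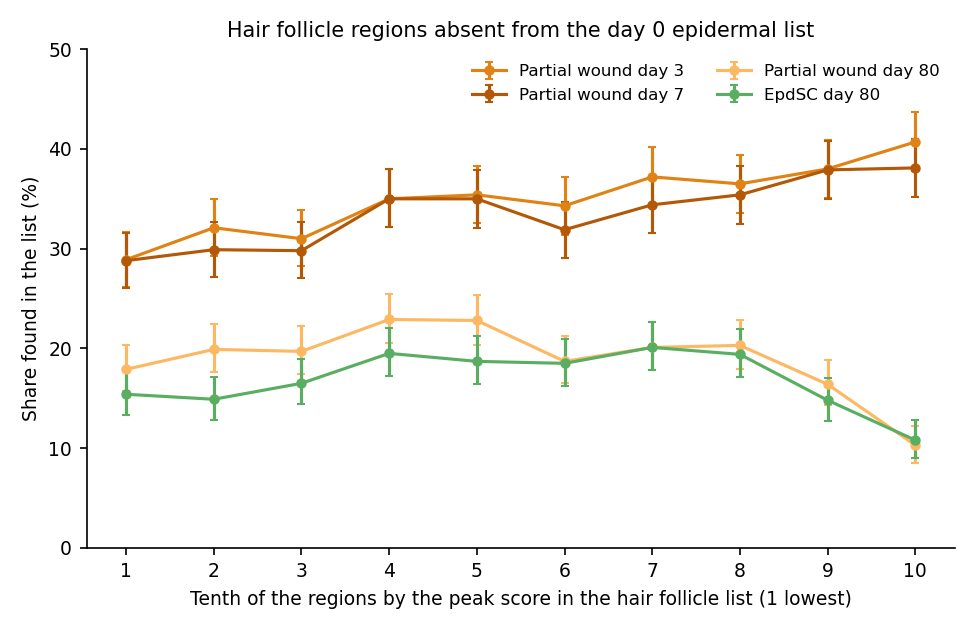
Share (%) of the 10897 hair follicle regions absent from the day 0 epidermal list that was found in 4 lists, by decile of their peak score in the hair follicle list (1 lowest), with 95% Clopper-Pearson bars. The day 3 share runs from 28.9% in the lowest decile to 40.7% in the highest, and the day 80 partial-thickness share is 17.9% and 10.3% at the same ends.

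Epidermal regions took the opposite course along the partial-thickness wound, and the full-thickness lists shared it. Bmp4 had 1 region at day 3, 2 at day 7 and 6 at day 80, the number of the day 0 epidermal list. The region 6669 bp from the gene (chromosome 14, 46397339 to 46399088) was in every list but the hair follicle list, while the regions at 46389838 to 46391359, 46408265 to 46408858, 46421737 to 46423225 and 46439252 to 46440123 were in both unwounded epidermal lists, absent at days 3 and 7 and present at day 80. Tgfb2 had 3 regions at day 3, 3 at day 7 and 8 at day 80, Dab1 4, 4 and 9, and Dlg2 14, 13 and 22. Robo1 differed, with 5, 12 and 10, a fall from day 7 to day 80 that left it under both unwounded epidermal lists. Of the 12093 epidermal regions absent from the hair follicle list, 44.6% (43.7 to 45.5) were in the day 3 list, 52.3% (51.4 to 53.2) in the day 7 list and 71.8% (71.0 to 72.6) in the day 80 list, beside 71.6% in the day 80 epidermal list. Of 34 such regions at BMP and TGF-beta genes, 13 were in the day 3 list, 19 in the day 7 list and 27 in the day 80 list. The day 80 epidermal list held 31 of them. The day 80 share exceeded the day 3 share by 27.2 points. In the full-thickness lists the shares were 52.6% (51.7 to 53.5) at day 7 and 70.7% (69.8 to 71.5) at day 80, with 2 and 5 regions at Bmp4 and 3 and 9 at Tgfb2.

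**Figure D3:**
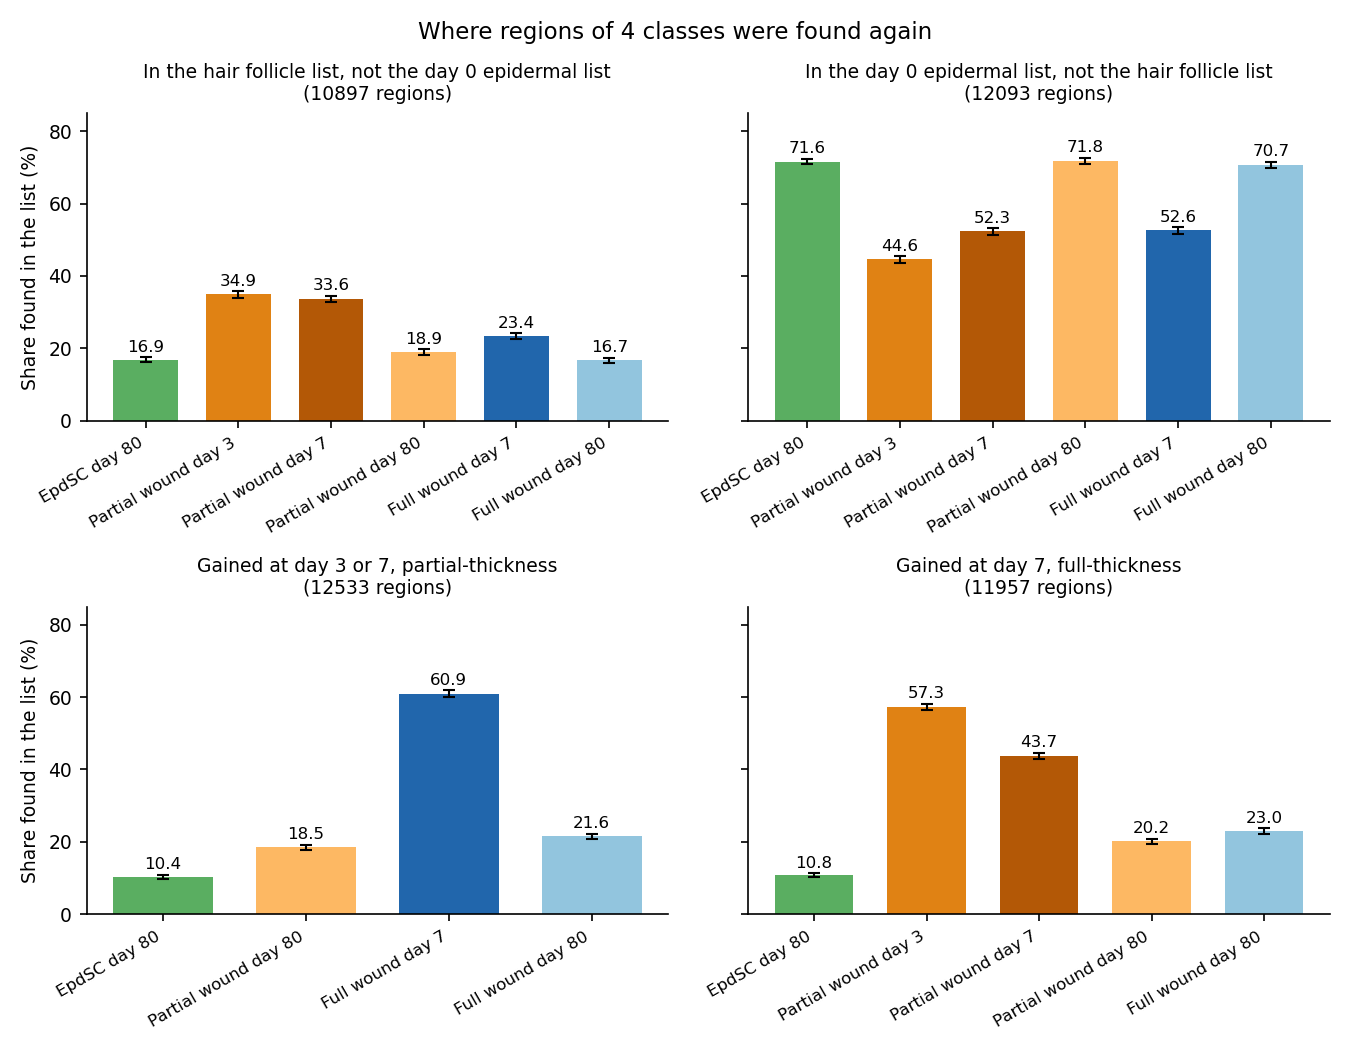
Share (%) of the regions of 4 classes found in each other list, with 95% Clopper-Pearson bars: hair follicle regions absent from the day 0 epidermal list, the reverse, and regions gained early in each wound type. Hair follicle regions have 34.9% in the day 3 partial-thickness list against 18.9% at day 80, and epidermal regions 44.6% against 71.8%.

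The early partial-thickness lists held regions that neither day 0 list had, among them regions of single wound epithelium and inflammation genes, although neither gene list as a whole stood apart from random lists. Itga5, a subunit of the fibronectin receptor, had 1 region in the day 0 epidermal list, 6 at day 3 and 4 at day 7, Epha2, a receptor tyrosine kinase gene, 2, 4 and 4, Plau, the urokinase gene, 3, 6 and 4, and Tgfa, an EGF receptor ligand gene, 4, 7 and 8. Notch3, a Notch receptor gene, had 1, 6 and 5, and Prdm1, which encodes a transcriptional repressor, 4, 9 and 9. Il1r2, a decoy receptor for interleukin 1, had 5, 9 and 9, and the chemokine gene Cxcl2 0, 2 and 2. Trp63 had 2, 16 and 12, although its 10 regions in the day 80 epidermal list place it among genes whose unwounded lists differ. The keratin gene Krt6a had 0, 2 and 2, and 2 in the hair follicle list. Its near-identical neighbour Krt6b could share its reads. In the hair follicle list Trp63 had 8 regions, Il1r2 and Tgfa 4 each and Prdm1 3. Itga5 and Plau had 2 each in that list, Epha2 and Notch3 1 each and Cxcl2 0.

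Such wound-gained regions numbered 12533, and 6572 with lists of equal length. Macrod2 (18), Atxn1 (16), the polarity gene Pard3 (14), Ank3 (12) and Rere (11) had the most. The day 80 partial-thickness list held 18.5% (17.8 to 19.2) of the wound-gained regions and the day 80 epidermal list 10.4% (9.8 to 10.9). The day 80 list of the other wound, full-thickness, held more of them, 21.6% (20.8 to 22.3), so the share is not particular to this wound. The difference between the partial-thickness and epidermal shares was 8.1 points. In strong regions the difference was 15.1 points. It was 18.3 when peaks had to cover 50% of a region, a rule that by itself favours the wider peaks of the day 80 wound list. Inflammation genes had 38 wound-gained regions, of which 9 were in the day 80 wound list and 7 in the day 80 epidermal list. BMP and TGF-beta genes had 17, of which 7 and 2 were. Wnt and hedgehog genes went the other way, with 17, of which 3 and 7 were, and hair follicle stem cell genes had 31, of which 3 and 3 were. A Notch3 region 2767 bp from the gene (chromosome 17, 32169664 to 32170616) was in all 5 wound lists and in no unwounded list. Wound epithelium genes (23.5%, percentile 83.8), inflammation genes (22.1%, percentile 74.1, and 54.0 among regions absent from the day 80 epidermal list as well), basal keratinocyte genes (21.8%, percentile 72.9) and AP-1 and stress genes (16.6%, percentile 20.8) did not stand apart from random lists in their share of wound-gained regions.

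The full-thickness wound list of day 7 held more regions than the day 0 epidermal list at several inflammation and wound epithelium genes. The genes given here, apart from Plaur, rank high for regions gained in this wound, a choice that favours such a rise. Housekeeping genes also rose in this longer list, from 58.3% to 77.8% of their regions. Inflammation genes rose from 52.3% to 73.8% and wound epithelium genes from 38.2% to 67.6%. Il33, an alarmin gene of epithelia, had 7 regions in the day 0 epidermal list and 13 at day 7, Il1a, a cytokine gene of keratinocytes, 3 and 6, Il19 0 and 3, and Irf1, an interferon response factor gene, 3 and 8. The collagenase gene Mmp13 had 0 and 4, Epha2 2 and 6, Itga5 1 and 5, and Plaur, the urokinase receptor gene, 0 and 3, with 3 in the hair follicle list as well. Smad3, which transmits TGF-beta signals, had 6 and 12, and Tgm3, a transglutaminase gene of cornification, 7 and 12. The unwounded day 80 epidermal list had 6 regions at Irf1, 8 at Smad3 and 9 at Tgm3, so part of these differences also lies between the unwounded lists. At day 80 the same genes had 7 (Il33), 1 (Il1a), 0 (Il19), 3 (Irf1), 2 (Mmp13), 3 (Epha2), 2 (Itga5), 2 (Plaur), 10 (Smad3) and 8 (Tgm3).

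In all, 11957 regions were in the day 7 full-thickness list and in neither day 0 list, and 5940 with lists of equal length. Atxn1 (17), Macrod2 (15), Pard3 (14), Rbms3 (12), the nuclear receptor gene Rora (12) and Pitpnc1 (11) had the most. Pitpnc1 had 5 regions in the day 0 epidermal list, 16 at day 7 and 5 at day 80. Wound epithelium genes (27.2%, percentile 96.7), terminal differentiation genes (32.7%, percentile 95.7) and inflammation genes (26.2%, percentile 94.9) were inside the band. Among wound-gained regions absent from the day 80 epidermal list as well, inflammation genes stood at percentile 85.3 and terminal differentiation genes at 91.2. In this narrower class 5 of 18 lists stood below the band and 0 above it, where chance would put 0.9 outside it. Among all wound-gained regions of this wound, hair follicle stem cell genes stood under the band (8.8%, percentile 0.4), and Lhx2 had 0 regions in the day 7 full-thickness list. The day 80 full-thickness list held 23.0% (22.2 to 23.8) of the wound-gained regions and the day 80 epidermal list 10.8% (10.3 to 11.4). The day 80 partial-thickness list held 20.2% (19.5 to 20.9). The difference of 12.2 points between the full-thickness and epidermal shares was 25.3 in strong regions. It turned to -1.3 when peaks had to cover 50% of a region, a setting that leaves 37.5% of the regions of the day 80 full-thickness list with its narrow peaks.

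At day 7 the wound types shared wound-gained regions at inflammation genes, among others. Both day 7 lists held wound-gained regions at Il33 (3 regions), the chemokine genes Ccl20 (3) and Cxcl2 (2), the calgranulin gene S100a8 (2) and Irf1 (4), at Itga5 (3), Epha2 (2) and Mmp13 (2), and at Pard3 (9), Atxn1 (7) and the Hippo pathway factor gene Tead1 (6). Of 172 regions at inflammation genes, 26 (15.1%) were wound-gained in both, against a median of 8.2% for random lists (percentile 99.6). Terminal differentiation genes had 17.3% (percentile 96.9) and muscle genes 22.2% of 9 regions, both inside the band, and 1 of 18 lists outside it is about the 0.9 that chance would give. The overlap was 5220 regions, 65.5% of the 7975 gained in the partial-thickness list of day 7 and 43.7% of those gained in the full-thickness list. Independent lists would share 4321 of the 22066 regions absent from both day 0 lists, a ratio of 1.21. Part of this excess may come from the shared day 0 lists, and with lists of equal length the overlap was 2440 regions. Only regions held by some list were counted, which raises the number expected of independent lists and lowers the ratio. The ratio is therefore no measure of how far the wounds share regions.

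At day 80 the wound lists held regions that neither unwounded epidermal list had. Itga6, an integrin gene of the hemidesmosome, had 5 regions in each unwounded epidermal list, 8 in the partial-thickness list and 7 in the full-thickness list. Socs3, a brake on cytokine signalling, had 5, 6, 9 and 7, Sik1, a kinase gene, 3, 4, 11 and 5, and Nxn 1, 5, 11 and 4. Ltbp1, which encodes a TGF-beta binding protein of the matrix, had 3, 1, 3 and 10, with 15 in the day 7 full-thickness list, and Nrg1, an ERBB ligand gene, 13, 11, 11 and 16. Smad3 had 6, 8, 11 and 10. Both day 80 wound lists held such regions at Atxn1 (4), Cdk6 (3), Nectin1 (3), Smad3 (2) and Krt17 (1).

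The partial-thickness list had 4511 regions in neither unwounded epidermal list (13.8% of its regions). Of these, 693 (15.4%) were also in the hair follicle list and in a day 3 or day 7 list, 199 (4.4%) in the hair follicle list without the early wound lists, 1550 (34.4%) in the early wound lists without the hair follicle list, and 2069 (45.9%) in neither. The full-thickness list had 4445, of which 530 (11.9%), 260 (5.8%), 1934 (43.5%) and 1721 (38.7%) fell in the same order, with day 7 as the early list. Both counts depend on the setting, from 263 in strong regions to 8999 with 50% cover for the partial-thickness wound, and from 350 in strong regions to 6739 with peaks reduced to their central 200 bp for the full-thickness wound, so that most of these regions are weak peaks.

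An unwounded list set apart in the same way gives the background for these shares. Of the 2506 regions in the day 0 epidermal list and neither other list of the partial-thickness trio, 48.4% (46.5 to 50.4) were in the early partial-thickness lists. For the 2994 in the day 80 epidermal list alone the share was 30.0% (28.3 to 31.6), and for the 4511 of the day 80 wound list 49.7% (48.3 to 51.2), so that the lists as deposited do not set the wound list apart from the day 0 epidermal list. The difference of 1.3 points (half-width 2.46) was 5.7 with lists of equal length, -8.2 with the central 200 bp and 10.4 with 50% cover, which favours the wider peaks of the wound list, so its direction depends on the setting. For the full-thickness trio the shares in the day 7 list were 27.9% (26.0 to 29.7), 22.9% (21.4 to 24.3) and 55.4% (54.0 to 56.9). That difference of 27.6 points over the day 0 epidermal list turned to -23.3 with 50% cover, which leaves few of the narrow peaks of the day 80 full-thickness list, and both full-thickness lists come from another driver line (Sox9-CreER) than both epidermal lists (Krt19-CreER). The share in the hair follicle list was 21.1%, 22.3% and 19.8% in the partial-thickness trio.

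The day 80 lists of both wounds shared 1401 of these regions, against 740 for independent lists (ratio 1.89 of 27106 regions absent from the unwounded epidermal lists). Both sets are defined by absence from the same epidermal lists, which alone can raise this overlap. Counting only regions held by some list works the other way and lowers the ratio. The ratio is therefore no measure of a shared wound effect. Of the 1401, 62.0% were in the day 3 partial-thickness list, 64.2% in the day 7 partial-thickness list, 70.2% in the day 7 full-thickness list and 26.1% in the hair follicle list. No gene list left the band in the partial-thickness regions. In the full-thickness regions the epidermal stem cell genes did (15.1%, percentile 98.3), with regions at Notch3, Ovol1, Klf4 and Grhl3, and so did the endothelial genes (17.6%, percentile 98.6), with percentile 97.3 when the window was 10 kb.

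Markers of other cell types were also counted, since sorted cells can carry others along. Immune genes had 8 of 20 regions (40.0%, percentile 98.0) among the wound-gained regions of the partial-thickness wound, 4 of them at Ptprc, which encodes CD45. The others lay at Laptm5 (2), Cd3e (1) and Itgam (1). Of the 17 immune genes found in the reference, only 8 had a region in any list. Endothelial genes had 17 of 51 (33.3%, percentile 97.9; percentile 95.1 when the window was 10 kb), with Pecam1 (6) and Flt1 (4) first. Pecam1 also had 6 regions in the day 80 epidermal list. Fibroblast genes had 0 of 27 (percentile 0.2), and 66.7% of their regions were in the hair follicle list, against 37.0% in the day 0 epidermal list and 14.8% in the day 7 partial-thickness list. No fibroblast region was assigned to Col3a1, Lum, Pdgfrb or Twist1. Melanocyte genes had 64.3% of their regions in the hair follicle list and 42.9% in the day 0 epidermal list, and Mitf had 11 and 6. Muscle genes had 9 regions, of which 33.3% were in the hair follicle and day 0 epidermal lists, 55.6% in the day 80 epidermal list, 66.7% in each partial-thickness list, and 77.8% and 66.7% in the full-thickness lists of days 7 and 80.

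Across whole lists, sebaceous gland and isthmus genes had 44.6% of their 65 regions in the day 0 epidermal list and 58.5% at day 3 of the partial-thickness wound, with Pparg at 0 regions in every unwounded list and 3 at day 3. Interferon genes had 58.1% and 54.8%, proliferation genes 64.3% and 81.0%, and housekeeping genes 58.3% and 75%, so that these reference genes also had more regions in the longer list.

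**Figure D4:**
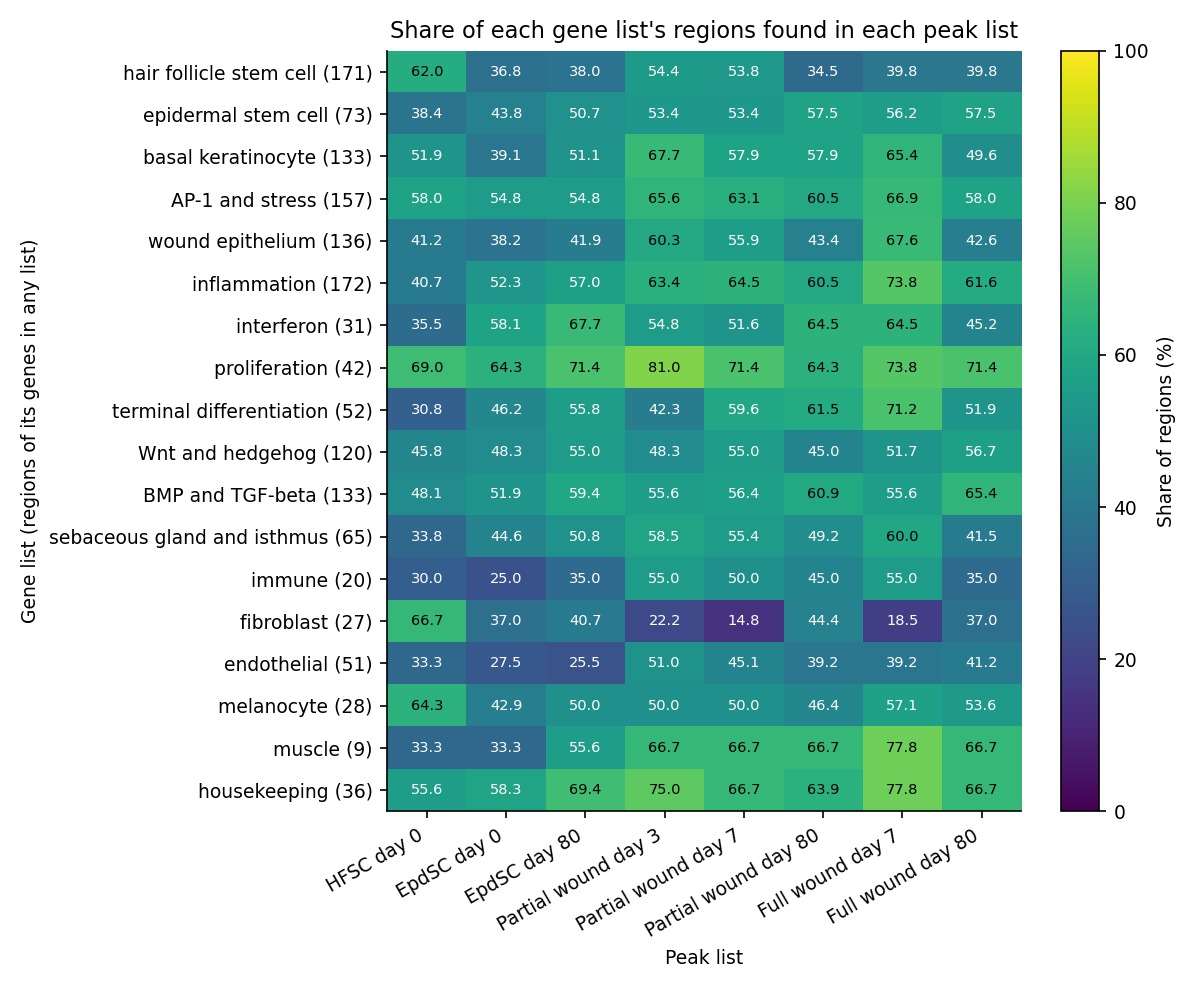
Share (%) of the regions assigned to the genes of each of 18 gene lists (vertical axis, with the number of regions) that was found in each of the 8 peak lists (horizontal axis); the colour runs from 0 to 100%. Hair follicle stem cell genes have 62.0% in the hair follicle list, 54.4% at day 3 and 34.5% at day 80 of the partial-thickness wound, and fibroblast genes have 66.7%, 22.2% and 44.4% in the same lists.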

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

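The comparison of single genes between the wound types and the count of sex-linked peaks were chosen after the values were seen, and none of the differences here was tested. The wound types also differ in the labelled origin of the cells and in the driver line. Effects of these cannot be told apart from that of the wound type. With 1 list per group no test of a group against its own replicates was possible.

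Lhx2 had 0 regions in the day 7 full-thickness list, 5 in the day 7 partial-thickness list and 3 in the day 0 epidermal list. Nfatc1 had 6 regions in the day 7 full-thickness list, against 9 in the partial-thickness list and 7 in the day 0 epidermal list. At day 80 the full-thickness list had 10 Nfatc1 regions, the partial-thickness list 6 and the epidermal list 7. Trp63 had 6 regions in the day 80 full-thickness list, 12 in the partial-thickness list and 10 in the epidermal list. Jun had 6 regions in the day 80 full-thickness list, 4 in the partial-thickness list and 5 in the epidermal list. Fos had 10 regions in the day 7 full-thickness list, 7 in the partial-thickness list and 9 in the day 0 epidermal list.

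On chromosome Y, the day 3 partial-thickness list had 3 peaks and the day 80 partial-thickness list 3, against 1 each in the hair follicle and day 0 epidermal lists and 0 in the others. Uty had 2 peaks in each of these wound lists and 1 each in the hair follicle and day 0 epidermal lists, and Eif2s3y had 1 in each of these wound lists. Xist had 1 peak in the day 80 epidermal list, 2 in the day 7 full-thickness list and 1 in the day 80 full-thickness list. The sex of the mice is not given in the sources used here.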

How the results depend on the processing

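The settings were planned except the strong regions, the gene end version and the list without Fbn1, which were chosen after the values were seen. No paired analysis was possible because each group has 1 list, and for the same reason no replicate could be left out. Motif alternatives were not run without genome sequence. A count is called moved when it changed by more than 1.5 times, and a share or difference when it changed by at least its 95% interval half-width. Limiting to autosomes, asking for absence within 500 bp, or merging only the compared lists kept all 35 region counts, shares and differences within these tolerances, and pairwise peak counts moved 2. Of the gene list shares, 282 stayed within them and 42 moved, 38 of these within 1 kb of a gene end. Of the named gene counts, 118 stayed and 2 moved.

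Strong regions are fewer by construction. They numbered 3249 for the hair follicle and 3914 for the day 0 epidermis against each other, 365 for day 0 and 350 for day 80 epidermis against each other, 2572 and 2760 gained in the partial- and full-thickness wound, 1088 gained in both at day 7, and 263 and 350 in the day 80 partial- and full-thickness lists alone. Lists of equal length gave 3863 for day 80 against day 0 epidermis, 6572 and 5940 gained in the wounds, 2440 gained in both, and 2898 and 2709 in the day 80 wound lists alone. With 50% cover there were 8285 for day 0 against day 80 epidermis, and 8999 and 2382 in the day 80 partial- and full-thickness lists alone, where the central 200 bp gave 7319 and 6739.

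The excess of hair follicle regions at day 3 over the day 80 epidermal list was 30.1 points with 50% cover, 12.5 with equal length, 15.8 with the central 200 bp and 23.3 in strong regions. At day 80 it was 16.1 with 50% cover and 0.7 in strong regions. The share of epidermal regions at day 80 less that at day 3 was 18.5 points with the central 200 bp and 37.9 in strong regions. The excess of regions gained in the partial-thickness wound at day 80 was 18.3, 7.2 and 15.1 with 50% cover, equal length and strong regions.

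Direction turned in 3 places. The excess of regions gained in the full-thickness wound was -1.3 with 50% cover, 10.4 with the central 200 bp and 25.3 in strong regions. For regions of the full-thickness day 80 list alone, the excess over the day 0 epidermal list was -23.3 with 50% cover, 31.3 with equal length, 8.9 with the central 200 bp and 44.1 in strong regions. For the partial-thickness list it was 10.4, 5.7 and -8.2 with 50% cover, equal length and the central 200 bp. The 50% rule keeps 37.5% of the regions of the day 80 full-thickness list, 64.5% of the day 80 epidermal list, 76.8% of the day 0 epidermal list, 93.7% of the day 80 partial-thickness list and 96.2% of the day 3 list, so differences under it follow peak width in part.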

Other observations

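The tests of explanations below were all chosen after the results had been seen.

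In all, 3606 regions were in both unwounded epidermal lists and in no wound list of day 3 or day 7, and 71.7% (70.2 to 73.1) of them were in the day 80 partial-thickness list and 61.6% (60 to 63.2) in the day 80 full-thickness list. The 8656 regions in both unwounded epidermal lists and not the hair follicle list were found there more often, at 83.4% and 80.3%, while 20.6% of the 3606 were also in the hair follicle list. Prlr, the prolactin receptor gene, had 7 such regions, Trpm3, a cation channel gene, 7, and Slit3, a guidance ligand gene, 8, beside long genes such as Dlg2 (15) and Pde4d (10). Prlr had 12 regions in each unwounded epidermal list, 3 and 4 in the partial-thickness lists of days 3 and 7, 2 in the full-thickness list of day 7, and 10 and 11 at day 80. Bmp4 had 4 such regions and Tgfb2 3. AP-1 and stress genes had few (1.9%, percentile 1.7), and were the 1 list below the band, while 1 other list stood above it.

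Regions gained early in a wound were found in the day 80 wound lists more often than in the day 80 epidermal list. They were chosen by absence from the day 0 epidermal list, which the day 80 epidermal list resembles most. Part of the excess can come from that choice. Longer lists and wider peaks do not account for the partial-thickness excess, which was 6.5 points for equal length and the central 200 bp together. The full-thickness excess was 10.1 points, so a longer list does not account for it. Wider peaks were no candidate there, as that day 80 list has narrower peaks than the epidermal one (median 460 against 641 bp). The 50% rule, with 18.3 and -1.3 points, decides nothing, as it keeps 93.7% of the partial-thickness, 37.5% of the full-thickness and 64.5% of the epidermal day 80 regions. In regions strong in the early wound lists the excess was 15.1 and 25.3 points, so weak calls in those early lists do not account for it. The day 80 calls were not filtered by strength, so weak calls near the threshold of a day 80 list are left open. Regions on the sex chromosomes do not account for the excess, with 8.2 and 12.2 points on autosomes. Leaving these regions out does not test a difference in sex between the mice of the lists. Xist had a peak in the day 80 epidermal and full-thickness lists and none in the day 80 partial-thickness list, which had peaks at Uty. For the partial-thickness wound the excess over the nearer unwounded list, each list being set apart in turn, was 1.3 points, 5.7 with equal length and -8.2 with the central 200 bp, so that an ordinary difference between lists cannot be told from a lasting trace of the wound. For the full-thickness wound it was 27.6 points and 8.9 with the central 200 bp, but both full-thickness lists come from Sox9-CreER mice and both epidermal lists from Krt19-CreER mice, so the driver line could give this as well as a lasting trace of the wound.

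Fibroblast genes held more hair follicle regions than random gene lists. Fibroblasts carried through the sort might give this, and 5 of 13 listed genes had such a region, which cannot tell; gates on an epithelial surface marker would remove them. A single gene with many regions does not account for it, as the list without Fbn1 stood at percentile 98.3. Whether hair follicle stem cells themselves have these regions open stays a hypothesis.

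Hair follicle regions were found at day 3 of the partial-thickness wound more often than in the day 80 epidermal list. Their choice by absence from the similar day 0 epidermal list can give part of this excess. Hair follicle stem cells sorted with the labelled progeny would give a larger excess at the strongest regions, and the excess was 13.5 points in the lowest decile and 29.9 in the highest, a difference of 16.4 points. Progeny that keep part of their hair follicle regions open would give the same, as a hypothesis. The day 7 full-thickness list, labelled as epidermal progeny, also held 23.4% of these regions against 16.9% in the day 80 epidermal list, so part of the excess could belong to wounding and not to hair follicle origin, unless that list holds hair follicle cells as well. These lists do not separate the explanations, and the gates of the sort are not given in the sources used here.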
